A study of Homo sapiens with 6 samples.

How the data were processed

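ATAC-seq peak lists of 6 libraries were analysed, 1 for each combination of genotype (CCRF-CEM parent or SLFN11 knockout) and treatment (DMSO, or 100 nM camptothecin for 2 h or 4 h). Per the labels' protocols, nuclei of treated cells were incubated with transposase and the tagged DNA was amplified by PCR. The submitters' processing notes name Trim Galore 0.6.2, Trimmomatic 0.39, BWA 0.7.17, SAMtools 1.8, Picard 2.9.2, MACS2 2.1.2 and the hg19 build, without saying what each was used for. Whether reads were shifted for the transposase offset, how reads were extended, how duplicates were treated and which background model was used are not given in the sources used here. Each of these choices can move peak edges and the number of peaks, and not necessarily by the same amount in every library, even with the same settings. Peaks were called per library and not on pooled reads, since each deposited list carries a single library code in its peak identifiers.

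Each deposited list gives, per entry, a position, a score, a fold enrichment of the summit over background, a -log10 p and a -log10 q. The score deposited by the authors equals 10 times the -log10 q, truncated to a whole number. The fold enrichment deposited by the authors is a ratio over local background made by their peak caller. In the comparisons of lists it was used only to describe and rank peaks within the list that holds them. Genotype-only regions were ranked by its lowest value over 3 libraries. Among the additional observations it served, with p, to recover pileup and background, and to form classes of peaks. The -log10 p and -log10 q deposited by the authors come from the same caller, and every list ends at a q of 0.01. Lists held 33916, 30767 and 18407 entries in the parent libraries recorded as DMSO, 2 h and 4 h, and 28251, 25533 and 25644 in the knockout libraries. Entries on the mitochondrial genome or chromosome Y, between 0.445% and 0.728% of a list, were left out of the comparisons. A region with several summits has several entries, and overlapping entries of a list were merged into 1 peak that keeps its highest fold and significance. Coordinates are hg19, counted from 1.

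The files are placed by the sample they are recorded under. Their library codes disagree with the codes in the sample titles for 3 of 3 libraries in each genotype, and the recorded order is the alphabetical order of the codes in 3 of 3. Both placements were computed. The recorded placement gives the main values and the title-code placement is an alternative fixed before the data were examined, as were the comparisons, the other alternatives and the rule for named peaks.

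Lists were compared by overlap of at least 1 bp. A peak is called missing or added when it meets no peak of the other list. Shares carry Wilson 95% intervals, and the interval of a log2 ratio of peak numbers is the Wilson interval of the corresponding share. Neighbouring peaks are not independent and amplified reads are not independent molecules, so these intervals cover counting error only. With 1 library per group no test between treatments was run. Regions of the union of all lists were formed by merging peaks that overlap in any library. Named peaks are the 5 of highest fold enrichment in each direction per comparison, in the list that holds them, and for genotype-only regions the 5 with the highest lowest fold over the 3 libraries. Of each set the text gives some or all, from the highest down. No filter for repeated or poorly mapped sequence was applied to them here. The wider peaks of at least 300 bp were added after the values were seen and are named as such.

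Read totals were not used here. Depth was instead read from the deposited values. Fold enrichment and p of a peak together fix the pileup at its summit and its background under a Poisson model, and the recovered pileup was within 0.02 of a whole number for at least 99.98% of entries in every list. For -log10 p above 280 the Poisson tail was summed on the log scale. The lowest background level rises with the number of reads and with the length to which reads are extended. It was 1.29, 1.26 and 1.22 in the parent libraries recorded as DMSO, 2 h and 4 h, and 1.37, 1.36 and 1.27 in the knockout libraries. Recovered pileups and backgrounds did not enter the counts of added and missing peaks, and serve only the comparisons of signal and depth among the additional observations. The median summit pileup was 27.0, 30.5 and 18.0 in the parent libraries and 21.0, 19.0 and 19.0 in the knockout libraries, so peaks near the threshold rest on few reads and their presence or absence is uncertain.

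Alternatives were a -log10 q of at least 5, an overlap of at least 50% of the shorter peak, lists shortened to the 14205 most significant peaks of each library, entries as deposited and the title-code placement. A further alternative, genotype-only regions without the parent library of fewest peaks, was added after the data were seen, as was a test of peak numbers between genotypes with the 3 treatments as pairs. Overlap calls were tested on simulated data made from the real lists with known peaks removed and added, for each of the 7 pairwise comparisons, and 100.0% of removed and of added peaks were found with either overlap rule, on lists of 14205 to 23665 peaks. Added peaks lay away from all real peaks and kept peaks were only slightly shifted, so this checks the code and not calls near a peak edge. Recovery of the pileup was tested on 1521 to 1576 simulated peaks per library and gave the true whole number in 100.0%. These peaks were made with the same formula and the same ranges for every library, so this checks the arithmetic alone. The work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.

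Promoters, gene lists fixed beforehand and the genomic and sequence context of peaks were planned but not run, because they need a genome and annotation of hg19, which were not used here. No gene is therefore named, the SLFN11 locus was not analysed here, and the knockout rests on the labels.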

Results

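Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open chromatin and tags it for sequencing, in CCRF-CEM cells, an established human T lymphoblast leukaemia line. The parent cells express SLFN11, a protein that binds stressed replication forks and sensitises cells to drugs that damage DNA, and were compared with SLFN11-knockout cells derived from them. Each genotype was treated with DMSO, the solvent, or with 100 nM camptothecin, an inhibitor that traps topoisomerase I on DNA, for 2 h or 4 h. The series title names chromatin remodelling by SLFN11 under replication stress as its subject. There was 1 library in each of the 6 groups, so no value has a replicate spread and no p-value is given for a treatment; 95% intervals are Wilson intervals and cover counting error only. Within each genotype, the library codes carried by the peak lists matched the codes in the titles of the samples they are recorded under in 0 of 3 cases. The recorded order was the alphabetical order of the codes in 3 of 3. By the title codes, the list recorded as DMSO is the 2 h camptothecin library, the list recorded as 2 h is the 4 h library and the list recorded as 4 h is the DMSO library. Libraries are therefore named below by their recorded sample, and counts of peaks under the title codes are given beside those under the recorded samples. SLFN11 itself and all other genes were not located, because no gene annotation of hg19, the build of the peaks, was used here.

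Among the parent libraries, accessible regions were fewest in the library recorded as 4 h of camptothecin. It held 14205 merged peaks on chromosomes 1 to 22 and X, against 23665 in the library recorded as parent DMSO and 21617 in the library recorded as parent 2 h. The 3 knockout libraries lay between these values, with 20894 peaks in the library recorded as DMSO, 19167 in that recorded as 2 h and 19289 in that recorded as 4 h. Peaks covered 12.1, 11.5 and 5.69 Mb in the parent libraries recorded as DMSO, 2 h and 4 h, and 9.09, 7.79 and 8.20 Mb in the corresponding knockout libraries. Median peak width was 452, 487 and 353 bp in the parent libraries and 381, 352 and 374 bp in the knockout libraries, in the same order. More than 1 summit was listed in 28.6%, 28.4% and 21.8% of the parent peaks and in 25.2%, 23.7% and 24.0% of the knockout peaks. By the title codes, the smallest parent list belongs to the DMSO sample.

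**Figure D1:**
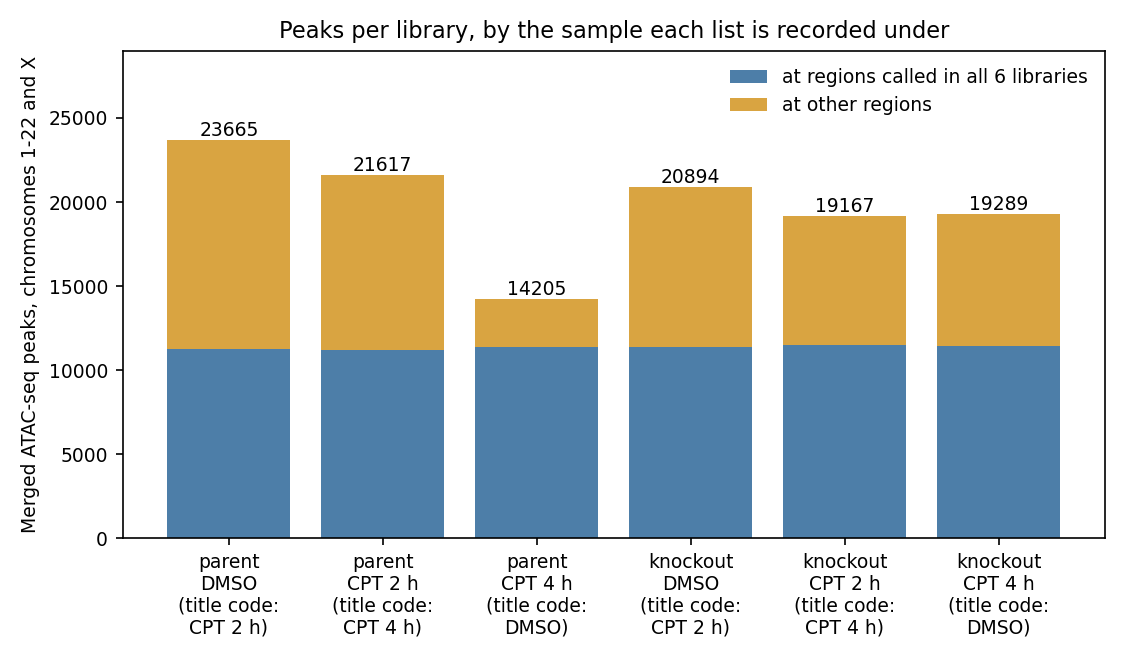
Bars give the number of merged ATAC-seq peaks on chromosomes 1 to 22 and X in each of the 6 libraries, split into peaks at regions called in all 6 libraries and peaks at other regions; the sample named by the title code is in brackets. The library recorded as parent 4 h has 14205 peaks and the other 5 have between 19167 and 23665.

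The union of the 6 lists held 32037 regions. All 6 libraries shared 11070 of them (34.6%, interval 34.0 to 35.1%), and 8745 (27.3%, 26.8 to 27.8%) were called in 1 library alone. The library recorded as parent 4 h lacked 2013 regions that the other 5 libraries all held, whereas the corresponding number for any other library was between 62 and 359. The parent libraries recorded as DMSO and 2 h shared 70.4% of the regions found in either. Sharing with the library recorded as parent 4 h was 52.9% for the first of these and 54.0% for the second. Pairs of knockout libraries shared between 66.5% and 67.8%, and pairs of different genotype between 58.6% and 65.3%. Pairwise sharing depends on list length, and its values are descriptions of these libraries.

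The effect of camptothecin in SLFN11-positive cells was read from the parent libraries. In the list recorded as 2 h, 4948 peaks of the DMSO list were missing (20.9%, 20.4 to 21.4%) and 2974 peaks were present that the DMSO list lacked (13.8%, 13.3 to 14.2%). In the list recorded as 4 h, 10739 DMSO-list peaks were missing (45.4%, 44.7 to 46.0%) and 1058 peaks were added (7.45%, 7.03 to 7.89%). Of the regions in the union, 6329 were held by both other parent libraries and not by this one. Relative to DMSO, the log2 ratio of peak numbers was -0.13 (-0.16 to -0.10) for the list recorded as 2 h and -0.74 (-0.77 to -0.71) for the list recorded as 4 h. By the title codes these directions turn, and the 2 h library adds 10739 peaks to the DMSO list and lacks 1058 (log2 ratio 0.74), while the 4 h library adds 9247 and lacks 1584 (log2 ratio 0.61). With lists of equal length, the library recorded as 4 h lacked 3088 and added 2846 peaks, and the library recorded as 2 h lacked 1686 and added 1717.

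In all 7 pairwise comparisons, missing peaks were narrower and lower than the shared peaks of the same list. Median widths of missing peaks ran from 192 to 277 bp, and those missing from the list recorded as parent 4 h were the widest and highest of these sets. Their median width was 277 bp against 637 bp for DMSO-list peaks shared with the 4 h list, and their median fold enrichment within the DMSO list, as given by the authors' peak caller, was 4.93 against 8.49. The highest of them was a 138 bp peak on chromosome 9, positions 44070657 to 44070794 of hg19, with a fold enrichment of 30.2; it was also absent from the list recorded as 2 h. Next came peaks on chromosome 4, 70296615 to 70296752 (27.2-fold), and chromosome 1, 120543915 to 120544082 (24.2-fold), followed by wider peaks on chromosome 9, 123883880 to 123884210 (15.7-fold, 331 bp), and chromosome 11, 102245171 to 102245730 (14.5-fold, 560 bp). The chromosome 4 peak and the wider chromosome 9 peak were each present in all 5 lists other than that recorded as parent 4 h. Peaks found in the 4 h list and not in the DMSO list were led by chromosome X, 61815091 to 61815236 (16.0-fold), chromosome 2, 89853148 to 89853286 (12.1-fold), chromosome 20, 29811929 to 29812134 (11.7-fold), chromosome 3, 179941003 to 179941294 (10.4-fold), and chromosome 7, 159792 to 159991 (10.3-fold). For the list recorded as 2 h, the highest added peaks were on chromosome 16, 35239604 to 35239736 (22.8-fold), chromosome 10, 35310585 to 35310733 (20.3-fold), and chromosome 5, 146587514 to 146587645 (19.5-fold). After the chromosome 9 peak, the highest missing ones were on chromosome 17, 45234284 to 45234432 (21.1-fold), and chromosome 4, 163342549 to 163342700 (19.3-fold). Under the title codes, the peaks missing from the list recorded as 4 h become peaks added at 2 h of camptothecin.

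**Figure D2:**
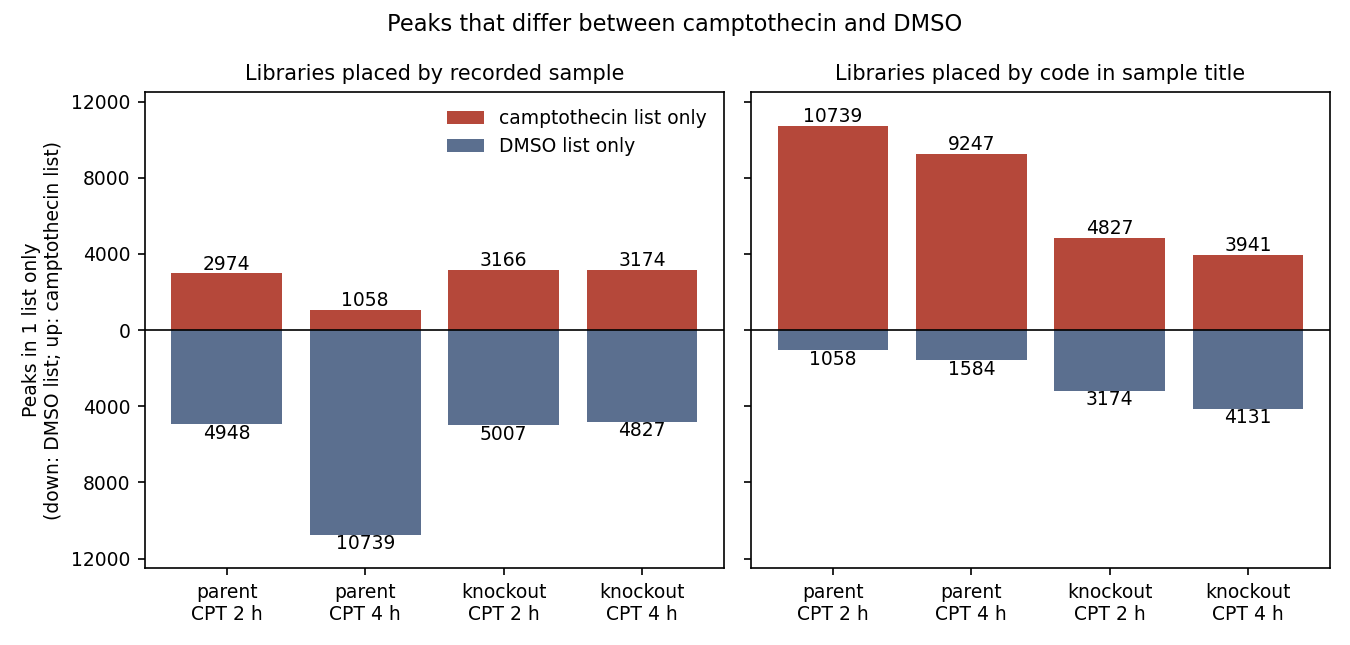
Bars above 0 count peaks found in the camptothecin list and not in the DMSO list, and bars below 0 count peaks found in the DMSO list and not in the camptothecin list, for 1 library per group. With libraries placed by recorded sample (left) the parent 4 h comparison has 1058 added and 10739 missing peaks; with libraries placed by title code (right) the parent 2 h comparison has 10739 added and 1058 missing.

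In SLFN11-knockout cells, both lists recorded as camptothecin lacked a smaller share of DMSO-list peaks than the list recorded as parent 4 h and a larger share than the list recorded as parent 2 h. The list recorded as 2 h lacked 5007 DMSO-list peaks (24.0%, 23.4 to 24.5%) and added 3166 (16.5%, 16.0 to 17.1%). The list recorded as 4 h lacked 4827 (23.1%, 22.5 to 23.7%) and added 3174 (16.5%, 15.9 to 16.98%). The log2 ratio of peak numbers to DMSO was -0.12 (-0.15 to -0.10) at 2 h and -0.12 (-0.14 to -0.09) at 4 h. By the title codes the 2 h library adds 4827 peaks and lacks 3174 (log2 ratio 0.12), and the 4 h library adds 3941 and lacks 4131 (log2 ratio -0.01, -0.04 to 0.02). With lists of equal length, 18.4% and 17.5% of DMSO-list peaks were missing from the knockout lists recorded as 2 h and 4 h. In the parent lists the shares were 11.9% and 21.7%. By the title codes, 20.0% of DMSO-list peaks were missing at 2 h in parent cells and 17.3% in knockout cells, so the order of the genotypes at 2 h turns in equal lists. In the full lists it did not turn. There the shares at 2 h were 20.9% in parent and 24.0% in knockout cells as recorded, and 7.45% and 16.5% by the title codes. The parent DMSO list by the title codes sets the equal length and is itself not shortened. The title-code comparison of 4 h with DMSO was not computed for equal lists. Whether the genotypes differ in these shares was not tested.

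Among knockout peaks that differed between lists, the highest fold enrichment was 58.4, at chromosome 7, 45291577 to 45291706, a 130 bp peak called in the list recorded as 2 h and in no other library. The list recorded as 2 h also added peaks on chromosome 9, 44070663 to 44070794 (32.0-fold), chromosome 16, 35239602 to 35239730 (28.0-fold), and chromosome 6, 133593993 to 133594136 (19.8-fold). These chromosome 9 and chromosome 16 sites were each called in 2 of the 6 lists. The list recorded as 4 h added peaks on chromosome 9, 70076689 to 70076828 (18.0-fold), chromosome 11, 48946392 to 48946637 (12.6-fold), and chromosome 1, 120543931 to 120544074 (11.7-fold). Both camptothecin lists lacked the DMSO-list peak on chromosome X, 61881320 to 61881552 (18.2-fold), which no other library held. The 4 h list further lacked peaks on chromosome X, 61815093 to 61815236 (14.1-fold), and chromosome 11, 77597505 to 77597672 (13.5-fold). Under the title codes, peaks added in the list recorded as 4 h become peaks missing at 2 h, and the peaks it lacked become added ones. Of the 54 peaks taken by highest fold over all pairwise comparisons, 38 were no wider than 170 bp, against 8.96 to 12.8% of all peaks in a list. No filter for repeated or poorly mapped sequence was applied here, and whether such narrow high peaks are open regions was not tested.

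Knockout and parent cells were compared at each recorded treatment. At DMSO the knockout list lacked 6249 parent peaks (26.4%, 25.8 to 27.0%) and added 3224 (15.4%, 14.9 to 15.9%), a log2 ratio of peak numbers of -0.18 (-0.21 to -0.15). At 2 h it lacked 6528 (30.2%, 29.6 to 30.8%) and added 3725 (19.4%, 18.9 to 20.0%), with a log2 ratio of -0.17 (-0.20 to -0.15). At 4 h the order turned, and the knockout list lacked 1643 parent peaks (11.6%, 11.1 to 12.1%) and added 6794 (35.2%, 34.6 to 35.9%), with a log2 ratio of 0.44 (0.41 to 0.47). Under the title codes this excess of knockout peaks belongs to DMSO, and the log2 ratio is -0.18 at 2 h and -0.17 at 4 h. With lists of equal length, which makes missing and added peaks nearly equal by construction, 2473 parent peaks were missing at DMSO, 3289 at 2 h and 2887 at 4 h as recorded. By the title codes these numbers belong to 2 h, 4 h and DMSO. Clone and genotype cannot be told apart with 1 knockout line.

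The highest parent peaks that the knockout lacked at DMSO were on chromosome 9, 44070657 to 44070794 (30.2-fold), chromosome 1, 120543915 to 120544082 (24.2-fold), and chromosome 6, 133593983 to 133594138 (22.5-fold). All of these sites were called in the knockout list recorded as 2 h, at 32.0, 15.2 and 19.8-fold, so they are not particular to parent cells. At 2 h the highest parent peaks that the knockout lacked were on chromosome 10, 35310585 to 35310733 (20.3-fold), chromosome 5, 146587514 to 146587645 (19.5-fold), and chromosome 11, 48899044 to 48899252 (16.5-fold). The chromosome 10 and chromosome 5 peaks were each called in 1 list alone. The chromosome 11 site was also called in the knockout lists recorded as DMSO (13.0-fold) and 4 h (15.4-fold). The highest knockout peaks missing from the parent list at 4 h were on chromosome 4, 70296616 to 70296753 (23.3-fold), and chromosome 6, 119558556 to 119558694 (23.2-fold). Among peaks of at least 300 bp, a limit chosen after the values were seen, the knockout lists lacked parent peaks on chromosome 17, 74099593 to 74099987 (12.1-fold, DMSO), and chromosome 16, 15187882 to 15188328 (15.3-fold, 2 h). These wide sites were called in 3 and 5 of the 6 lists. The knockout list at 4 h added peaks of this width on chromosome 13, 28033715 to 28034127 (10.7-fold), and chromosome 5, 175395040 to 175395388 (10.1-fold), both of which were held by all 5 libraries other than that recorded as parent 4 h.

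Regions present in all 3 libraries of 1 genotype and in none of the other do not depend on which library is which treatment. There were 99 such parent-only regions (0.309% of the union, 0.254 to 0.376%) and 229 knockout-only regions (0.715%, 0.628 to 0.813%). The parent-only region with the highest lowest fold enrichment lay on chromosome 14, 55804531 to 55804763, with 8.54, 6.80 and 7.97-fold in the libraries recorded as DMSO, 2 h and 4 h. It was followed by chromosome 14, 44272520 to 44273076 (557 bp), chromosome 2, 207395529 to 207395750, chromosome 7, 50535593 to 50535977, and chromosome 12, 133463989 to 133464599, where the lowest fold was between 5.98 and 6.22. In knockout cells the leading region was chromosome 6, 119558556 to 119558703, at 17.9, 20.4 and 23.2-fold, which was only 148 bp wide, followed by chromosome 7, 155142954 to 155143103, at 9.62, 10.2 and 10.6-fold and 150 bp. Wider knockout-only regions lay on chromosome 7, 13840523 to 13840992 (470 bp, lowest fold 7.83), chromosome 10, 85836428 to 85836733 (306 bp, 6.74), and chromosome 15, 48332442 to 48332786 (345 bp, 6.62). The parent-only number rests on the library with the fewest peaks, and without it 1551 regions were held by both other parent libraries and by no knockout library, against 301 knockout-only regions. With only peaks of -log10 q of at least 5, the knockout-only number was 128.

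Peaks missing from the list recorded as parent 4 h were found on every chromosome examined, at different shares. The share of DMSO-list peaks without a 4 h peak ranged from 36.0% on chromosome 4 (33.2 to 38.9%) to 54.4% on chromosome 22 (49.97 to 58.8%), with 54.1% on chromosome 17 (51.3 to 56.8%). In the knockout comparison of the lists recorded as 4 h and DMSO, the corresponding share was lowest on chromosome 19, at 17.7% (15.5 to 20.1%), and highest on chromosome 18, at 31.6% (27.3 to 36.4%). Chromosomes 17, 19 and 22, which are rich in genes and were grouped after the values were seen, held 12.7% of peaks in the parent list recorded as DMSO, 14.1% at 2 h and 10.7% at 4 h. In the knockout lists they held 11.6%, 10.6% and 11.2%. By the title codes the order DMSO, 2 h and 4 h reads 10.7%, 12.7% and 14.1% in parent and 11.2%, 11.6% and 10.6% in knockout cells. On these 3 chromosomes together the parent list recorded as 4 h lacked 51.1% of DMSO-list peaks (49.3 to 52.8%), against 44.6% (43.9 to 45.2%) on the 20 others, and 2.05% of its own peaks (1.45 to 2.89%) were absent from the DMSO list, against 8.09% (7.63 to 8.58%). Within the group, chromosome 19 was at 46.9% (44.1 to 49.6%), below chromosome 18 at 50.6% (45.8 to 55.4%) and chromosome 21 at 51.1% (45.2 to 56.9%). The direction differed between comparisons. The knockout list at 2 h lacked 38.5% of the parent 2 h peaks on these chromosomes (36.8 to 40.3%) and 28.8% on the others (28.2 to 29.5%), whereas the parent list recorded as 2 h lacked 11.2% of DMSO-list peaks on them (10.1 to 12.3%) and 22.3% on the others (21.8 to 22.9%), which by the title codes compares 4 h with 2 h of camptothecin. For knockout against DMSO the shares were 24.7% and 23.9% at 2 h and 20.6% and 23.4% at 4 h, and for knockout against parent 26.5% and 26.4% at DMSO and 8.20% and 12.0% at 4 h.

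**Figure D3:**
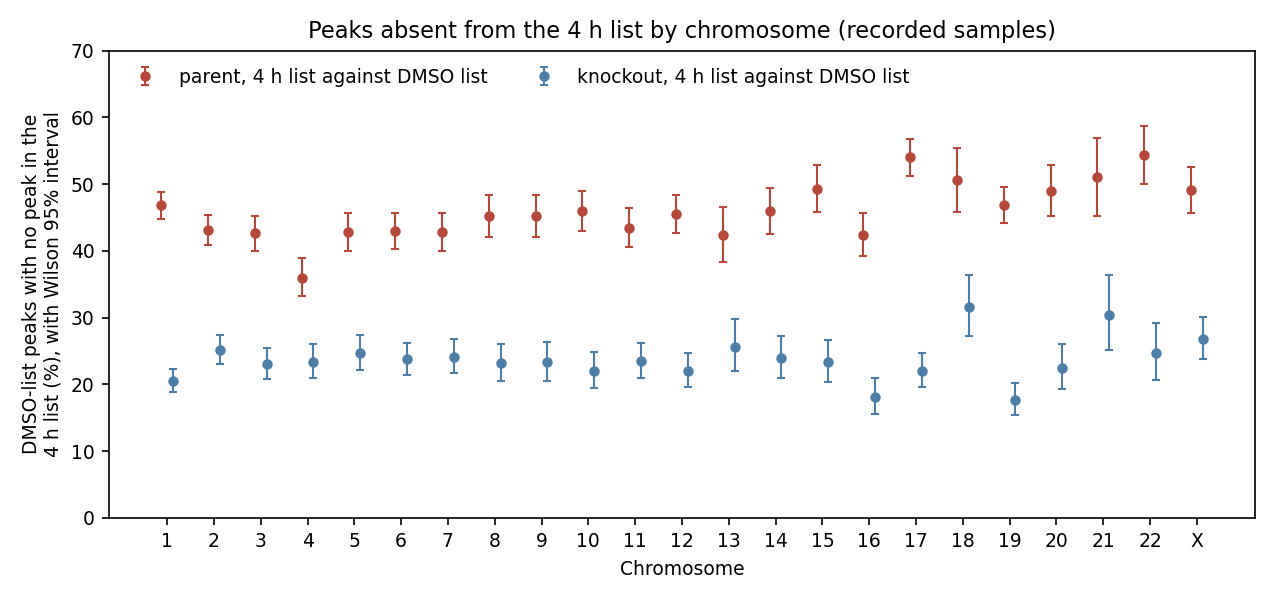
Points give the percentage of DMSO-list peaks on each chromosome that had no peak in the list recorded as 4 h, for parent and knockout cells, and bars are Wilson 95% intervals. Parent values run from 36.0% on chromosome 4 to 54.4% on chromosome 22 and knockout values from 17.7% on chromosome 19 to 31.6% on chromosome 18; by the title codes the same peaks are found at 2 h and not at DMSO.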

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

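The tests of mitochondrial reads, of the recorded sample, of a uniform scaling by matched shares, of all groups of 3 chromosomes and of the narrow peak were chosen after the result was seen; the others were fixed before it.

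The library recorded as parent 4 h held 14205 peaks, against 21617 and 23665 in the other parent libraries. Fewer reads alone do not account for this, since thinning the other parent libraries to its background level left them with 1.48 and 1.61 times its peaks, and mitochondrial reads took at most an estimated 12.5% of its reads, against up to 9.38% in the other parent libraries, with a genome of 2.7e+09 bp assumed. Signal was lower at shared sites too: over the 11070 regions called in all 6 libraries, its summit pileup over background had a median log2 ratio of -1.17 to the library recorded as parent DMSO, and only 6.09% of regions were higher. Its median summit pileup over background there was 16.4, against 38.0 and 46.9 in the parent libraries recorded as DMSO and 2 h. The knockout libraries recorded as DMSO, 2 h and 4 h were also low, at 21.9, 17.6 and 20.5. Yet the knockout library recorded as 2 h kept 1.27 times the 14205 peaks after thinning. This does not decide whether lower signal alone explains the peak number, because the shared regions had to be called in the smallest list too. They hold 11383 of its 14205 peaks, against 11482 of 19167 in that knockout library, so sites too weak for the smallest list are not compared. The lower signal may come from the treatment or from the preparation of this library, which 1 library per group does not separate. A wrong sample record is also open, since the library code differs from the title code of the recorded sample in 3 of 3 parent libraries. In each genotype the recorded order is the alphabetical order of the codes in 3 of 3 libraries. If the title codes hold, the library is the DMSO one, and camptothecin adds 10739 peaks at 2 h and 9247 at 4 h.

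Peaks of chromosomes 17, 19 and 22, grouped after the values were seen, were together missing from the library recorded as parent 4 h more often than others, although chromosome 19 alone was not high before matching (46.9%). A larger number of near-threshold peaks there does not account for it, since averaged over 5 classes of fold enrichment the gap was 7.53 percentage points (bootstrap 95% interval 5.995 to 9.07, with no allowance for the choice of chromosomes), and matched on fold and p together it was 8.86 points (7.47 to 10.2) against the library recorded as DMSO and 15.4 points (14.0 to 16.9) against that recorded as 2 h. To allow for the choice, the gap after removing class means was computed for all 1771 groups of 3 chromosomes: this group had the largest, at 8.73 points, and 1000 shuffles of chromosomes within classes gave at most 3.70 for any group, with chromosome 19 itself 6.08 points above its classes and chromosomes 18 and 21 at -0.07 and 0.187. The bootstrap and the shuffles treat neighbouring peaks as independent. They do not measure variation between libraries, so they do not show whether the gap would recur. The test of a single scaling of signal over the genome that was fixed beforehand met its bound of 0.1, with a log2 difference at shared regions of -0.07 (-0.10 to -0.04). The matched shares, which argue against such a scaling within these lists only, were added after that. A bias with GC content, in which these chromosomes are rich, and a response of gene-rich chromatin both remain open and were not tested, as no hg19 sequence was used here.

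The knockout-only peak on chromosome 6, 119558556 to 119558703, was 138, 147 and 139 bp wide in the 3 knockout libraries, at most 1.14 times the narrowest peak of its list. Of peaks of at least 10-fold, 0.428%, 2.07% and 0.415% were as narrow. Its width is what drew attention to it, so these values do not decide between a short fragment present in many copies and an open region, and no biological explanation was tested.

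Median peak width moved in opposite directions between DMSO and 2 h as recorded, by a log2 ratio of 0.11 in parent and -0.11 in knockout cells, a difference that was not tested. Under the title codes the median goes from 353 to 452 bp at 2 h and 487 bp at 4 h in parent cells, and from 374 to 381 bp and 352 bp in knockout cells, so that the opposite directions fall at 4 h and not at 2 h. In the mitochondrial peaks left out of the comparisons, the median summit pileup over background was 13547, 13269 and 17918 in the parent libraries recorded as DMSO, 2 h and 4 h and 14960, 14148 and 15045 in the knockout libraries, so that the highest value of each genotype belongs to DMSO under the title codes.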

How the results depend on the processing

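Placing libraries by title code moved most time-course values, by construction, since it exchanges whole lists. The log2 ratio of peak numbers turned to 0.74 (parent 2 h), 0.61 (parent 4 h), 0.12 (knockout 2 h), 0.44 (knockout against parent, DMSO) and -0.17 (knockout against parent, 4 h), and moved to -0.0092 for knockout 4 h. Added and missing peaks became 10739 and 1058 for parent 2 h, 9247 and 1584 for parent 4 h, and 4827 and 3174 for knockout 2 h. For knockout against parent they became 6794 and 1643 at DMSO and 3725 and 6528 at 4 h. Peak numbers became 14205 for parent DMSO and 21617 for parent 4 h. The other 11 values stayed within 1.5 times or their counting interval, including both genotype-only numbers, which do not depend on it.

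With -log10 q of at least 5, added peaks were 1821 (parent 2 h), 525 (parent 4 h), 1789 (knockout 2 h), 2023 (knockout 4 h), 1588 (knockout against parent, DMSO) and 1896 (the same, 2 h). Missing peaks for knockout against parent at 4 h were 967, and knockout-only regions 128. The log2 ratio of peak numbers was -0.92 for parent 4 h, -0.18 for knockout 2 h, and -0.30, -0.36 and 0.50 for knockout against parent at DMSO, 2 h and 4 h. No direction turned in any of these, and shorter lists give fewer peaks by construction. With 14205 peaks in every library, added and missing peaks were 1717 and 1686 (parent 2 h), 2846 and 3088 (parent 4 h) and 2992 and 2887 (knockout against parent, 4 h). Missing peaks were 2614 (knockout 2 h), 2485 (knockout 4 h), 2473 (knockout against parent, DMSO) and 3289 (the same, 2 h), and parent-only regions 149. Leaving out the parent library of fewest peaks, chosen after seeing the data, gave 1551 parent-only regions. An overlap of 50% of the shorter peak left all 14 counts of added and missing peaks within 1.5 times, as did entries as deposited for all 6 peak numbers.

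A ratio of peak numbers has no meaning for equal lists or another overlap rule and was not computed there. The promoter window, the matching of random lists and all alternatives for promoters and gene lists were not run, for lack of an hg19 annotation. With 1 library per group no samples share replicate numbers beyond 1; taking the genotypes as pairs by treatment, chosen after seeing the data, gave a mean log2 ratio of peak numbers of 0.03 (SD 0.36, 3 pairs, 2 of them lower in the knockout), with an exact two-sided sign-flip p of 1.00, where 3 pairs allow no p below 0.25. The 3 pairs are the same under the title codes. Missing peaks were low in the lists that held them, with a median fold between 4.31 and 4.93 over the 7 comparisons, and whether depth accounts for this was not tested.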

Other observations

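The 11070 regions called in all 6 libraries had to pass the threshold in every list, so sites too weak for the smallest list are not among them. At these regions the knockout libraries had lower signal than the parent libraries recorded as DMSO and 2 h. The median log2 ratio of summit pileup over background, knockout over parent, was -0.76 at DMSO, where 8.80% of regions were higher in the knockout, and -1.35 at 2 h, where 10.8% were higher. At 4 h as recorded it was 0.30 and 78.4% were higher. Under the title codes the signs at DMSO and at 4 h turn, with 0.30 at DMSO, -0.76 at 2 h and -1.35 at 4 h. As recorded, the ratio to DMSO was 0.25 at 2 h and -1.17 at 4 h in parent cells, with 70.1% and 6.09% of regions higher, and -0.25 and -0.08 in knockout cells. Under the title codes it was 1.17 at 2 h and 1.47 at 4 h in parent cells, with 93.9% and 90.5% of regions higher, and 0.08 and -0.17 in knockout cells. Peaks at these shared regions were also widest in the parent libraries recorded as DMSO and 2 h, with medians of 674 and 683 bp, against 403 bp in that recorded as 4 h and 537, 474 and 502 bp in the knockout libraries recorded as DMSO, 2 h and 4 h.

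Peaks that differed between lists mostly lay more than 10 kb from any peak of the other list. No comparison with random positions was made, so whether they lay nearer or farther than random positions is not known. Of the 10739 peaks missing from the list recorded as parent 4 h, 21.5% (20.8 to 22.3%) lay within 10 kb of a peak of that list, at a median distance of 33.4 kb. For the peaks missing from the knockout list recorded as 4 h the values were 29.4% (28.1 to 30.7%) and 25.5 kb. Distances grow as the other list gets shorter, and the shortest list is that recorded as parent 4 h.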
